A study of Mus musculus with 12 samples.

How the data were processed

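Total RNA from 12 mouse heart samples was measured on Agilent single-colour (Cy3) gene expression arrays, with 1 array per sample. The samples form 4 groups of 3: wild-type hearts (WT), wild-type hearts after myocardial infarction (WT+MI), hearts of mice transgenic for the long non-coding RNA CCRR (TG), and transgenic hearts after infarction (TG+MI). Groups and replicate numbers were taken from the labels. The titles of WT+MI 2 and WT+MI 3 carry another prefix than that of WT+MI 1, and these samples were placed by their characteristics. The strain is stated only for WT and WT+MI, so a strain difference between wild-type and transgenic samples cannot be told apart from the transgene. The time between infarction and sampling, and whether samples of a group came from separate animals, are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

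Per the labels, RNA was extracted with RNAiso Plus, checked on a Bioanalyzer, cleaned on columns with DNase treatment, and amplified and labelled with the Low Input Quick Amp kit. Spot intensity was measured and background-subtracted with Agilent Feature Extraction, per the file headers, and the processed Cy3 signal was deposited as linear intensity, not normalized between arrays. Each array has 62976 features, of which 59305 are spots of non-control probes. A value table of the same arrays was also deposited by the authors on a log2 scale. Each of its columns ranked the probes as the processed signal of its own array did (Spearman at least 0.99999 with its own array and at most 0.962 with any other), and its column medians lay between 4.22 and 4.23, which is what log2 of quantile-normalized intensity gives. That normalization was read from the values, since its steps are not given in the sources used here. The submitters' processing notes name limma without a version or a role.

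The deposited intensity of each array was taken to log2, the array's 75th percentile over non-control probes was subtracted, and spots of a probe were averaged after outlier spots were left out. In all, 49 probes were left out because every spot was an outlier on some array. Probe names were brought up to date through a RefSeq gene table. By accession 32994 probes matched, 10224 by current symbol and 520 by synonym, 12867 kept the name in the files, and 2055 symbols changed. Each gene was represented by the probe with the highest mean over the 12 arrays. Genes were tested where that probe was well above background on all 3 arrays of at least 1 group, which left 19761 of 36981. Probe coordinates are those of the files, on the mm9 build. The share of probes well above background, between 47.0% and 55.2% of probes per array, and the number of arrays limit the precision.

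Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 and the data.table package, version 1.17.8. All 12 arrays entered a single group-means model, so that the groups shared an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were WT+MI against WT, TG against WT, TG+MI against WT+MI, TG+MI against TG, and the interaction, which is the infarction response of transgenic hearts minus that of wild-type hearts. Slide 1 held WT 1 to 3, WT+MI 1 to 3, TG 1 and TG 2, slide 2 held TG 3 and TG+MI 1 to 3, and each slide was scanned separately from the other. Slide was fitted as a block, and comparisons were repeated within a slide where it held both groups. In the blocked model the slide effect rests on TG 3 against TG 1 and TG 2, so the blocked difference of TG from WT is that of TG 1 and TG 2 on slide 1, and that of TG+MI from TG is taken from TG 3 alone. TG+MI and WT+MI share no slide. On slide 1 the WT arrays lay in row 1 and TG 1 and TG 2 in row 2, so the block and the single slide do not remove a row effect from TG against WT.

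Before the data were examined, 30 gene lists, the rule for named genes, the comparisons and the alternatives other than those named as later additions were fixed. The lists cover Toll-like receptor signalling, inflammatory cytokines and chemokines, inflammasome and pyroptosis, interferon-stimulated genes, markers of monocytes and macrophages, neutrophils, lymphocytes, antigen presentation and dendritic cells, extracellular matrix and fibrosis, resident fibroblasts, cardiomyocyte contractile genes, cardiac stress genes, fatty acid oxidation, oxidative phosphorylation and citrate cycle, glycolysis and hypoxia, cardiac conduction and ion channels, endothelium, smooth muscle and pericytes, cell cycle, cell death regulators, epicardium, adipocytes, skeletal muscle, atrium, erythroid cells, lung, thymus, immediate early and heat shock genes, circadian clock and sex-linked genes. Some genes stand on 2 lists, such as Il1b and Tgfb1. Lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was also run with an estimated correlation, under which 0 of the lists called at the preset value passed. The thymus list had 1 tested member of 6 and was not tested.

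The named genes of a comparison were the 8 highest and 8 lowest log2 differences among called genes whose replicates did not overlap between groups and whose probe was well above background on all 3 arrays of the higher group, leaving out clone, predicted and accession names. To them were added the 2 members with the smallest p of the 6 lists with the smallest camera p and of the Toll-like receptor list, and always Tlr2, Tlr4, Myd88, Il1b, Il6, Tnf, Nfkb1, Nppa, Nppb, Myh6, Myh7, Col1a1 and Gja1. A few genes chosen by this rule are not reported here. Names that are only probe identifiers, or those of ribosomal pseudogenes and Platr transcripts, were also left out, a choice made after the values were seen. Further list members are given as examples within their lists. Where a probe was not well above background on any array of a group, a difference is given as at least N-fold: the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own signal and the lowest signal of any probe well above background, as means of normalized log2 values.

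Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, probes above background on all 12 arrays, slide or replicate number as a block, the mean of a gene's probes, every probe on its own, trend and robust variance estimates, array weights, a single slide, only the groups compared, a log2 difference of at least 1, an adjusted p under 0.01, fry in place of camera, and leaving out each array in turn. The removal of arrays that stood apart was added after the data were seen. For comparisons that share arrays, correlations of log2 differences are given beside 100 simulations of unchanged groups.

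The procedure was tested on simulated data with 200 changed genes among 19761 in 10 simulations per comparison. Among genes changed by 1 on the log2 scale, 67.3% were recovered for TG+MI against WT+MI, 69.6% for TG+MI against TG and 33.3% for the interaction. Among genes changed by 2 on that scale, the shares were 93.9%, 94.1% and 85%. False calls made up 4.54%, 4.49% and 5.00% of calls. The simulated noise was normal, independent between genes and equal in spread between groups, with no slide effect and no array that stood apart. These rates therefore check the procedure and may not hold for the measured comparisons.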

Results

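Expression was profiled in 12 mouse heart samples, 3 in each of 4 groups: WT, WT+MI, TG and TG+MI. The study asks whether CCRR, a long non-coding RNA, limits inflammation after infarction and whether Toll-like receptors take part. Among 59305 non-control spots, 0 carry the name CCRR, so the transcript of the transgene itself is not reported. The 75th percentile of the processed signal lay between 198 and 374 per array, 0 spots were saturated, and the lowest Spearman correlation between any 2 arrays was 0.909. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were well above background on all 12 arrays and Xist on 0.

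The first principal component held 55.5% of the variance and separated the infarcted hearts from the others. The WT arrays lay at -47.8, -51.9 and -50.4 on it, the TG arrays at -41.6, -43.9 and -46.6, the TG+MI arrays at 7.74, 35.9 and 4.39, and the WT+MI arrays at 107, 70.1 and 57.2. The second component, with 13.7%, set the TG arrays (-60.0, -30.1 and -25.2) apart from the WT arrays. TG+MI 3 stood alone on the third (9.05%), at -66.8. Differences below are on the log2 scale with limma's standard error, and each group has n = 3.

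WT+MI was compared with WT to measure the response to infarction in wild-type hearts. Inflammatory, cardiac stress and immediate early gene lists were higher, and mitochondrial, contractile and ion channel lists were lower, though not with an estimated correlation. Lcn2, which encodes the neutrophil protein lipocalin 2, was higher in WT+MI by 6.93 ± 0.27 (limma adjusted p = 1.06e-06), and Hmox1, the inducible haem oxygenase, by 5.36 ± 0.22 (adjusted p = 1.06e-06). Spp1, which encodes osteopontin, was higher by 9.61 ± 1.29 (adjusted p = 0.000407) and the cytokine gene Il1b by 6.98 ± 0.54 (adjusted p = 3.91e-05), with 1 of 3 WT arrays well above background for each. Inmt, a methyltransferase gene, was lower by -3.86 ± 0.51 (adjusted p = 0.000373), and Kcnip2, an auxiliary subunit of the transient outward potassium channel, by -2.48 ± 0.33 (adjusted p = 0.000405). In all, 9464 of 19761 genes (47.9%) passed, 3674 higher and 5790 lower, and 1534 and 1696 of these differed by at least 1 on the log2 scale.

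Of 33 tested cytokine and chemokine genes, 24 rose and 2 fell, and the same numbers passed adjusted over the list alone. Their median was 3.42, or 2.52 with genes below background in a group at their bound (camera adjusted p = 4.72e-10, and adjusted p = 0.229 with an estimated correlation). Ccl2, a monocyte chemoattractant, was higher by 4.83 ± 0.39 and Cxcl5, a neutrophil chemoattractant, by 6.99 ± 0.53 with 2 of 3 WT arrays above background, while Cxcl9 was lower by -2.09. Il6 was at least 50.4-fold higher (limma adjusted p = 0.000276), and Tnf differed by -0.26 ± 0.18 (adjusted p = 0.256). Of 14 neutrophil markers, 9 rose and 2 fell, as when adjusted over the list alone, with a median of 4.48 (4.33 at the bound, camera adjusted p = 5.58e-05, and adjusted p = 0.379 with an estimated correlation). S100a8 and S100a9, subunits of calprotectin, were higher by 4.99 ± 0.49 and 4.85 ± 0.44. The granule gene Camp was lower by -1.84 and Ltf at least 1.68-fold. Of 28 monocyte and macrophage markers, 13 rose and 0 fell, as when adjusted over the list alone, with a median of 0.85 (camera adjusted p = 1.35e-05, and adjusted p = 0.379 with an estimated correlation). Arg1, which encodes arginase 1, was at least 119-fold higher (adjusted p = 0.000362).

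Of 42 tested Toll-like receptor genes, 19 rose and 7 fell (21 and 7 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.000546, and adjusted p = 0.379 with an estimated correlation). Cd14, the co-receptor of Tlr4, was higher by 2.84 ± 0.35 (limma adjusted p = 0.0003), Tlr2, a receptor of bacterial lipoproteins, by 1.74 ± 0.31 (adjusted p = 0.00158), Myd88, the adaptor of most Toll-like receptors, by 1.48 ± 0.15 (adjusted p = 0.00011), and Tlr4, the receptor of lipopolysaccharide, by 0.66 ± 0.13 (adjusted p = 0.00217, with 3 probes between 0.66 and 2.17). Those that fell included Sigirr and Tollip, which restrain this signalling (-1.01 ± 0.17 and -0.34). Nfkb1 differed by 0.19 (adjusted p = 0.185). Of 14 inflammasome genes, 8 rose and 0 fell, as when adjusted over the list alone. Their median was 0.77 (camera adjusted p = 0.00105, and adjusted p = 0.379 with an estimated correlation). Of 20 cell death regulators, 11 rose and 2 fell (11 and 3 adjusted over the list alone). Their median was 0.88 (camera adjusted p = 0.000339, and adjusted p = 0.379 with an estimated correlation). Among them were Bax (1.32) and Ripk3 (2.05). Of 15 antigen presentation genes, 6 rose and 1 fell, as when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 0.0424, and adjusted p = 0.722 with an estimated correlation). That call was lost without WT+MI 1 (median 0.70, adjusted p = 0.26) and without WT+MI 2 (0.84, adjusted p = 0.0518).

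Of 16 cardiac stress genes, 14 rose and 0 fell, as when adjusted over the list alone. Their median was 1.74 (camera adjusted p = 4.67e-10, and adjusted p = 0.0689 with an estimated correlation). Nppa and Nppb, the natriuretic peptide genes, were higher by 2.51 ± 0.39 and 1.15 ± 0.14, and Gdf15, a stress cytokine, by 4.80 ± 0.46. Of 17 immediate early and heat shock genes, 16 rose and 0 fell, as when adjusted over the list alone. Their median was 2.63 (camera adjusted p = 6.09e-10, and adjusted p = 0.379 with an estimated correlation). Examples were Fos at 5.10 and Hspa1a at 5.17. Of 36 extracellular matrix genes, 18 rose and 5 fell (19 and 5 adjusted over the list alone). Their median was 0.59 (camera adjusted p = 9.17e-05, and adjusted p = 0.42 with an estimated correlation). Timp1, a protease inhibitor, was higher by 6.18 ± 0.50 and Thbs1 by 4.84 ± 0.52, Comp was lower by -2.14, and Col1a1 differed by 0.03 ± 0.34 (adjusted p = 0.94). Of 24 glycolysis and hypoxia genes, 11 rose and 0 fell, as when adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.0022, and adjusted p = 0.542 with an estimated correlation). An example was the lactate transporter gene Slc16a3 (5.61 ± 0.39).

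Of 35 oxidative phosphorylation and citrate cycle genes, 0 rose and 21 fell, as when adjusted over the list alone. Their median was -0.46 (camera adjusted p = 0.000167, and adjusted p = 0.722 with an estimated correlation). Of 28 fatty acid oxidation genes, 1 rose and 19 fell (1 and 20 adjusted over the list alone). Their median was -0.59 (camera adjusted p = 0.000837, and adjusted p = 0.722 with an estimated correlation). Ppara, a regulator of these genes, was lower by -1.34 ± 0.24, and the gene that rose was Pdk4 (1.46), a kinase that restrains pyruvate oxidation. Of 26 contractile genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone). Their median was -0.50 (camera adjusted p = 0.00373, and adjusted p = 0.722 with an estimated correlation). An example was the phospholamban gene Pln at -1.37 ± 0.23. Of 40 conduction and ion channel genes, 2 rose and 23 fell (2 and 25 adjusted over the list alone). Their median was -0.65 (camera adjusted p = 0.00105, and adjusted p = 0.379 with an estimated correlation). Kcnd2, a subunit of the transient outward channel, was lower by -1.90 ± 0.23. The connexin gene Gja1 differed by -0.35 ± 0.34 (adjusted p = 0.409). Myh6 and Myh7, the myosin heavy chain genes, differed by -0.16 and -0.19 without passing.

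Both groups lay on slide 1, so the slide block left these differences as they were and called 9235 genes. The atrial markers had a median of 1.63 and 0 of 4 passed (camera adjusted p = 0.525), and on WT+MI 1 they lay 4.41 above their mean over all arrays, against -4.41 and -4.10 on the other WT+MI arrays.

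**Figure D1:**
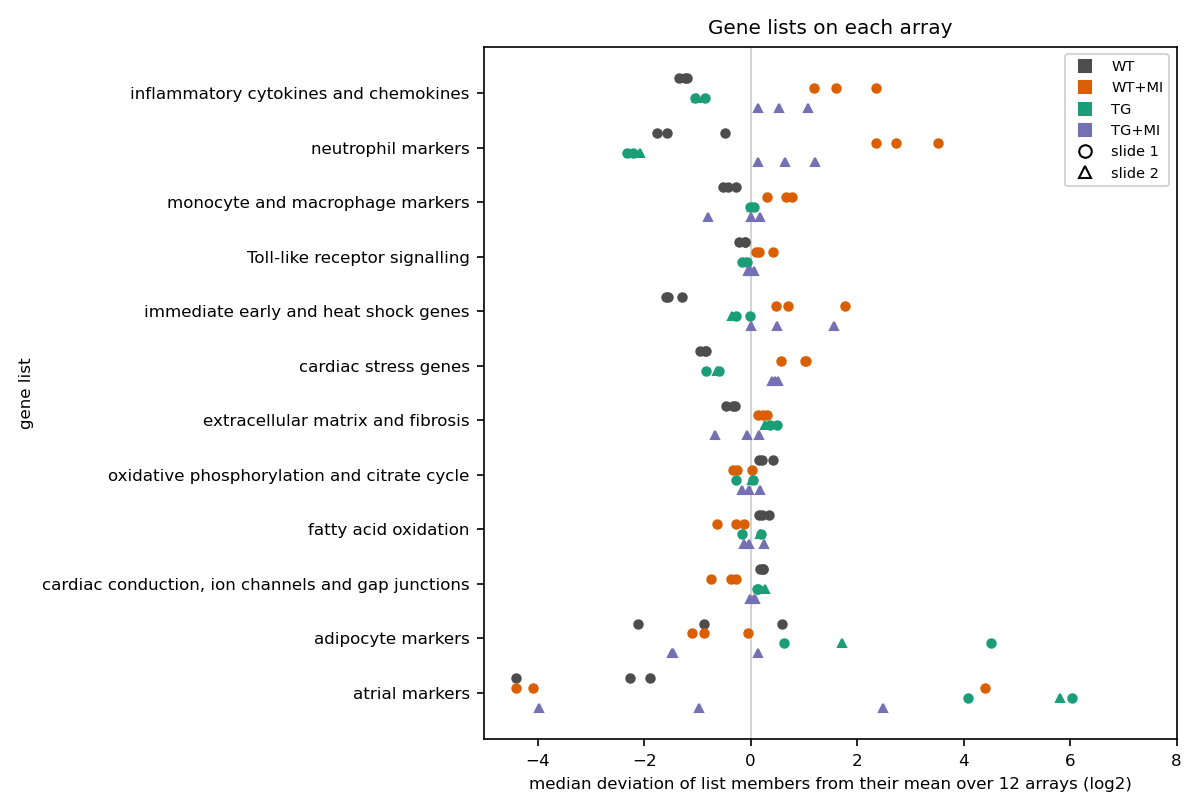
Median deviation of the tested members of 12 gene lists from their mean over the 12 arrays (log2 scale, horizontal axis), with a point per array coloured by group, circles for slide 1 and triangles for slide 2. The cytokine, macrophage, neutrophil and stress lists were higher in WT+MI than in WT, and the atrial list was high on the TG arrays (6.04, 4.09 and 5.81) and on WT+MI 1 and TG+MI 2.

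TG was compared with WT to measure the effect of the transgene without infarction. The matrix, immediate early, atrial and adipocyte lists were higher in TG by camera, and the erythroid and mitochondrial lists were lower, none of them with an estimated correlation. Some matrix, immediate early and atrial genes passed singly, but no adipocyte, erythroid or mitochondrial genes did. The Toll-like receptor and cytokine lists did not pass. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, was higher by 3.50 ± 0.33 (limma adjusted p = 0.00128, slide-blocked 3.71 with adjusted p = 0.0035), with 1 of 3 WT arrays above background. Cilp2, a cartilage matrix gene, was at least 16.3-fold higher (5.74 ± 0.60, adjusted p = 0.00261, blocked adjusted p = 0.0106), Hamp, which encodes the iron hormone hepcidin, at least 32.6-fold (7.31 ± 1.04, adjusted p = 0.00771, blocked adjusted p = 0.0263), and Mlana at least 40.7-fold (6.16 ± 0.69, adjusted p = 0.00383, blocked adjusted p = 0.0114). Nppa was higher by 2.82 ± 0.39 (adjusted p = 0.0074, blocked 2.71 with adjusted p = 0.023). Prdm1, a transcriptional repressor, was lower by -2.61 ± 0.27 (adjusted p = 0.00238, blocked -2.65 with adjusted p = 0.00991). In all, 518 genes (2.62%) passed, 294 higher and 224 lower.

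Of 36 extracellular matrix genes, 12 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 3.77e-19, and adjusted p = 0.281 with an estimated correlation). The median was 1.08 with the slide block (adjusted p = 1.37e-19) and on slide 1 alone (adjusted p = 3.36e-23). Comp, Eln and Bgn, which encode a cartilage matrix protein, elastin and biglycan, were higher by 2.95 ± 0.43, 2.54 ± 0.44 and 0.95 ± 0.17, and Col1a1 differed by 1.39 ± 0.34 (limma adjusted p = 0.0617). Of 13 resident fibroblast markers, 1 rose (Mfap5, 1.18 ± 0.22) and 0 fell, as when adjusted over the list alone, with a median of 0.42 (camera adjusted p = 7.45e-05, and adjusted p = 0.322 with an estimated correlation, blocked median 0.61 with adjusted p = 1.44e-05, the same median on slide 1 with adjusted p = 6.43e-06). Of 28 monocyte and macrophage markers, 1 rose (C1qb, 0.64 ± 0.12) and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 4.36e-05, and adjusted p = 0.504 with an estimated correlation, blocked median 0.29 with adjusted p = 0.000223, on slide 1 adjusted p = 2.37e-05). The slide block left 9 matrix genes, 0 fibroblast markers and 0 macrophage markers called, so the calls of Mfap5 and C1qb were lost.

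Of 17 immediate early and heat shock genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.87 (camera adjusted p = 1.94e-09, and adjusted p = 0.322 with an estimated correlation). The blocked median was 1.07 (adjusted p = 3.05e-09), as on slide 1 (adjusted p = 4.36e-10). Dusp1, a phosphatase of MAP kinases, was higher by 2.07 ± 0.23 and Nr4a1, a nuclear receptor, by 2.68 ± 0.38. Of 16 cardiac stress genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.00187, and adjusted p = 0.322 with an estimated correlation, blocked 0.18 with adjusted p = 0.0028). Among the stress genes was the metallothionein gene Mt2 (2.66 ± 0.24), while Nppb differed by -0.30 on slide 1 (limma adjusted p = 0.295 there). Of 35 oxidative phosphorylation genes, 0 passed singly, also when adjusted over the list alone, and their median was -0.33 (camera adjusted p = 1.01e-07, and adjusted p = 0.588 with an estimated correlation, blocked -0.37 with adjusted p = 3.61e-07, on slide 1 adjusted p = 2.39e-06). Of 26 contractile genes, 0 passed, with a median of -0.25 (camera adjusted p = 0.0131, and adjusted p = 0.701 with an estimated correlation, blocked -0.29 with adjusted p = 0.0144, on slide 1 adjusted p = 0.0215). That call was lost without WT 2 (median -0.15, adjusted p = 0.113) and TG 1 (-0.15, adjusted p = 0.116), and the median was -0.01 after quantile normalization and 0.09 in the authors' table. The block called 4 immediate early and 2 stress genes.

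Of 4 atrial markers, 2 rose (4 adjusted over the list alone), with a median of 8.26 (camera adjusted p = 2.83e-05, and adjusted p = 0.322 with an estimated correlation, blocked 7.98 with adjusted p = 0.000137, on slide 1 adjusted p = 0.000529). Myl4, the atrial essential light chain, was higher by 6.92 ± 1.57 (limma adjusted p = 0.0476, blocked adjusted p = 0.104). Of 9 adipocyte markers, 0 passed (6 higher adjusted over the list alone), with a median of 3.40 (camera adjusted p = 3.29e-05, and adjusted p = 0.322 with an estimated correlation, blocked 3.69 with adjusted p = 2.16e-05, on slide 1 adjusted p = 2.04e-05). Their median deviation was 4.51 on TG 1 but 0.63 and 1.71 on TG 2 and TG 3, against 0.60 on WT 2. Of 8 erythroid markers, 0 passed (8 lower adjusted over the list alone), with a median of -2.10, or -2.05 at the bound (camera adjusted p = 2.34e-05, and adjusted p = 0.322 with an estimated correlation, blocked -2.50 with adjusted p = 7.75e-06, on slide 1 adjusted p = 1.43e-05). Their median deviation was 3.09 on WT 1 but 0.44 and 0.90 on WT 2 and WT 3. Of 5 epicardial markers, 1 rose (3 adjusted over the list alone), Msln, at least 9.66-fold, and the median was 1.27 (camera adjusted p = 0.0364, and adjusted p = 0.322 with an estimated correlation, blocked 1.62 with adjusted p = 0.0144, on slide 1 adjusted p = 0.033). That call was lost without WT 2 (median 1.22, adjusted p = 0.105), TG 1 (0.74, adjusted p = 0.0951) and TG+MI 3 (1.27, adjusted p = 0.0789). With the block 1 epicardial gene was called and 0 atrial, adipocyte and erythroid genes.

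Of 42 Toll-like receptor genes, 1 rose and 0 fell, as when adjusted over the list alone. Their median was -0.04 (with a mean of the opposite sign, camera adjusted p = 0.737, blocked -0.05 with adjusted p = 0.757). The gene that rose was the kinase gene Ripk1 (0.46 ± 0.10, limma adjusted p = 0.0418), whose probes ranged from -0.27 to 0.46. Tlr2, Tlr4 and Myd88 differed by 0.15, 0.09 and -0.05 (adjusted p of 0.851, 0.78 and 0.905). Of 33 cytokine genes, 1 rose (Ptgs2, which encodes cyclooxygenase 2, at least 2.67-fold) and 2 fell, as when adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.477, blocked -0.18). Of 14 neutrophil markers, 0 rose and 3 fell (0 and 4 adjusted over the list alone), among them S100a9 (-2.07 ± 0.44, blocked -2.30 with adjusted p = 0.0561), but the list did not pass (median -0.27, camera adjusted p = 0.0667). Gja1 differed by -0.98 ± 0.34 (adjusted p = 0.166). With the block 0 Toll-like receptor and cytokine genes and 1 neutrophil gene were called.

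With the slide block 320 genes were called, 272 of them shared with the 518, and slide 1 alone called 432, of which 296 were shared. The count was 159, 137 and 162 without WT 1, WT 2 and WT 3, 243, 298 and 320 without TG 1, TG 2 and TG 3, and 866 without TG+MI 3. Of the 22 named calls, 10, 11 and 10 were lost without WT 1, WT 2 and WT 3 and 10, 8 and 10 without TG 1, TG 2 and TG 3, with Myl4, Ripk1 and S100a9 among them each time, and 2, 1, 2 and 3 without WT+MI 2, WT+MI 3, TG+MI 1 and TG+MI 2.

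TG+MI was compared with WT+MI to ask whether inflammation after infarction was lower with the transgene. The cytokine, neutrophil, macrophage and cell death lists were lower in TG+MI by camera, and the ion channel and fatty acid oxidation lists were higher, none of them with an estimated correlation. These groups share no slide, and with the slide block 0 genes passed in limma (1469 at an unadjusted p under 0.05), so blocked values are given beside the lists and some of the genes, none of which passed with the block. Hmox1 was lower by -1.95 ± 0.22 (limma adjusted p = 0.0181), Il1b by -3.03 ± 0.54 (adjusted p = 0.0242, blocked -2.09 with adjusted p = 0.668), S100a8 by -3.01 ± 0.49 (adjusted p = 0.0239, blocked -3.38 with adjusted p = 0.648) and Ankrd22 at least 5.12-fold (-4.07 ± 0.45, adjusted p = 0.0181). Kcnd2 and Kcnip2 of the transient outward current were higher by 1.19 ± 0.23 and 1.44 ± 0.33. In all, 2405 genes (12.2%) passed, 1539 higher and 866 lower, and 275 and 444 of these differed by at least 1 on the log2 scale.

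Of 33 cytokine and chemokine genes, 0 rose and 12 fell (0 and 14 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 8.16e-09, and adjusted p = 0.254 with an estimated correlation, blocked -0.92 with adjusted p = 4.44e-05). Besides Il1b, they included the neutrophil chemoattractants Cxcl2 and Cxcl3 (-2.69 and -3.19), Ccl2 (-1.46 ± 0.39), Tgfb1 (-0.77 ± 0.13) and Il1rn (-3.20), which encodes the natural antagonist of interleukin 1. Il6 differed by -0.57 (limma adjusted p = 0.661) and Tnf by 0.12 (adjusted p = 0.667). Of 14 neutrophil markers, 0 rose and 7 fell (1 and 9 adjusted over the list alone). Their median was -2.23 (camera adjusted p = 1.5e-05, and adjusted p = 0.254 with an estimated correlation, blocked -1.51 with adjusted p = 8.7e-06). Examples were Cxcr2 at -3.01 ± 0.44 and S100a9 at -2.72 ± 0.44. Of 28 monocyte and macrophage markers, 0 rose and 9 fell (1 and 15 adjusted over the list alone). Their median was -1.10 (camera adjusted p = 2.69e-07, and adjusted p = 0.386 with an estimated correlation, blocked -1.09 with adjusted p = 8.7e-06). Among them were Ccr2 (-2.70), Lgals3 (-2.03 ± 0.52) and Cd68 (-1.17 ± 0.32). Of 15 antigen presentation genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone). Their median was -1.0 (camera adjusted p = 9.01e-06, and adjusted p = 0.435 with an estimated correlation, blocked -0.79 with adjusted p = 0.001). On TG+MI 1, 2 and 3 the median deviations were 0.0160, 0.17 and -0.81 for macrophage markers and -0.21, 0.09 and -1.07 for antigen presentation genes, so TG+MI 3 stood apart in both.

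The Toll-like receptor list, which the series title concerns, had 1 member that rose and 7 that fell among 42 (2 and 10 adjusted over the list alone). Its median was -0.24 (camera adjusted p = 0.000266, and adjusted p = 0.386 with an estimated correlation, blocked -0.26 with adjusted p = 0.00156), and -0.10 without WT+MI 1. Cd14 was lower by -1.94 ± 0.35 (limma adjusted p = 0.0242, blocked -1.58 with adjusted p = 0.666), Tlr2 by -1.42 ± 0.31 (adjusted p = 0.029, blocked -1.24 with adjusted p = 0.668) and Myd88 by -0.56 ± 0.15 (adjusted p = 0.039, blocked -0.68 with adjusted p = 0.666). Tlr13 and Tlr6 were lower by -1.47 ± 0.34 and -1.94 ± 0.52, and the kinase gene Irak1 was higher by 0.35 ± 0.09. Tlr4 differed by -0.34 ± 0.13 (adjusted p = 0.0959) and Nfkb1 by -0.29 (adjusted p = 0.0983). Of 14 inflammasome genes, 0 rose and 5 fell (1 and 8 adjusted over the list alone). Their median was -0.57 (camera adjusted p = 4.16e-05, and adjusted p = 0.287 with an estimated correlation, blocked -0.66 with adjusted p = 0.00232). Examples were Aim2 at -1.27 and Gsdmd, the pore-forming gasdermin, at -0.67. Of 20 cell death regulators, 0 rose and 8 fell (1 and 10 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 1.83e-06, and adjusted p = 0.254 with an estimated correlation, blocked -0.42 with adjusted p = 9.7e-05). Examples were Bax at -0.90 ± 0.14 and Ripk3 at -1.28 ± 0.22.

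Of 40 conduction and ion channel genes, 12 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.000308, and adjusted p = 0.386 with an estimated correlation, blocked 0.39 with adjusted p = 0.0011). Besides Kcnd2 and Kcnip2, Kcnh2 and Kcnk3, which encode further potassium channels, were higher by 1.22 ± 0.27 and 1.07 ± 0.24. Gja1 differed by -0.33 ± 0.34 (limma adjusted p = 0.52). Of 28 fatty acid oxidation genes, 2 rose, Ppara (1.2 ± 0.24) and Acot1 (1.18 ± 0.24), and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 0.000194, and adjusted p = 0.638 with an estimated correlation, blocked 0.22 with adjusted p = 0.0238). Of 36 matrix genes, 1 rose and 6 fell (1 and 9 adjusted over the list alone). Their median was -0.47 (camera adjusted p = 9.01e-06, and adjusted p = 0.386 with an estimated correlation, blocked -0.23 with adjusted p = 0.217). Examples were Fn1 at -1.78 ± 0.41 and Timp1 at -1.78 ± 0.50. Of 16 stress genes, 0 rose and 3 fell (0 and 5 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 8.59e-05, and adjusted p = 0.254 with an estimated correlation, blocked -0.52 with adjusted p = 0.000807). Nppa differed by -1.05 (adjusted p = 0.0897). Gt(ROSA)26Sor, a widely expressed non-coding transcript, had the highest difference among the named genes, 3.19 ± 0.49 (adjusted p = 0.0239, blocked 4.11 with adjusted p = 0.572), with its 3 probes between 0.21 and 3.19.

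Single arrays decided much of this count. It was 0 without TG+MI 1 (5313 at an unadjusted p under 0.05 in limma), 4 without TG+MI 3, 45 without WT+MI 1, 1020 without WT+MI 2, 1037, 877 and 940 without WT 1, WT 2 and WT 3, and 1283 and 1528 without TG 2 and TG 3. Of the 30 named calls, 30, 29 and 25 were lost without TG+MI 1, TG+MI 3 and WT+MI 1. Atrial markers lay 4.41 above their mean on WT+MI 1 and 2.48 above it on TG+MI 2, and without both arrays 1626 genes passed. Without TG 1 and TG+MI 3, which stand apart from their groups, 0 passed (6029 at an unadjusted p under 0.05). The standard errors and p-values of this comparison also rest on the spread shared by all 4 groups, the uninfarcted ones included. With only the WT+MI and TG+MI arrays in the fit, which also leaves fewer arrays to estimate the spread, 0 of the 2405 calls held.

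**Figure D2:**
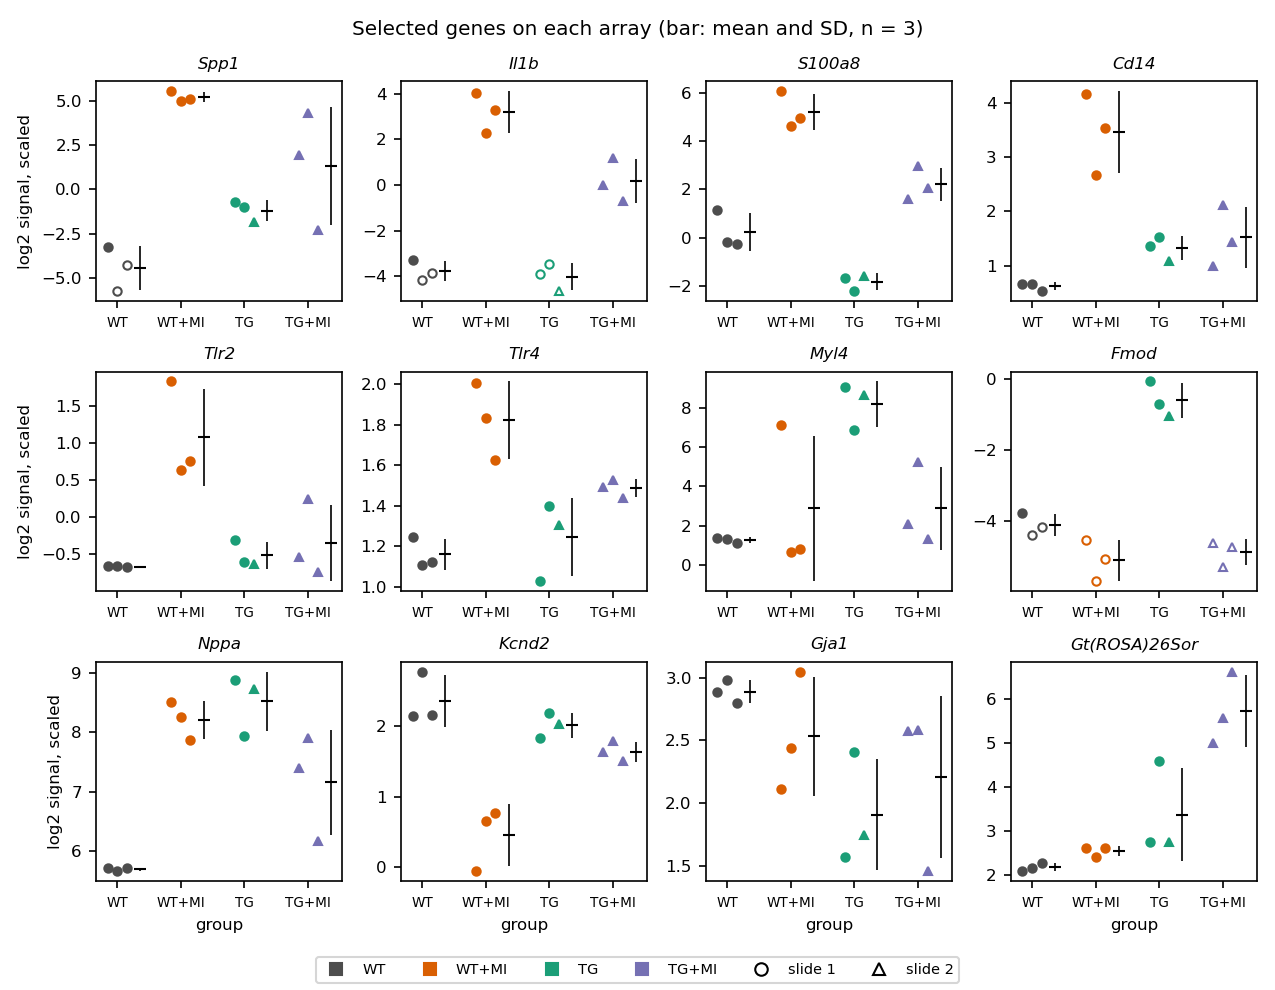
Normalized log2 signal of 12 genes on each array by group, relative to the array's 75th percentile, with open markers for probes not well above background, circles for slide 1, triangles for slide 2 and bars for the mean ± SD (n = 3). Il1b, S100a8, Cd14 and Tlr2 were higher in WT+MI than in WT and lower in TG+MI than in WT+MI, whereas Tlr4 and Gja1 did not pass between TG+MI and WT+MI.

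TG+MI was compared with TG to measure the response to infarction in transgenic hearts. The cytokine, neutrophil, stress and glycolysis lists were higher by camera, and the matrix, fibroblast, atrial and adipocyte lists were lower, none of them with an estimated correlation. Lcn2 was higher by 5.56 ± 0.27 (limma adjusted p = 6.8e-06, slide-blocked 5.32 with adjusted p = 0.00128), Hmox1 by 3.19 ± 0.22 (adjusted p = 8.83e-05, blocked 3.49 with adjusted p = 0.00225) and Ccl2 by 4.17 ± 0.39 (adjusted p = 0.000359, blocked 4.50 with adjusted p = 0.0134). Cxcl5 was higher by 5.87 ± 0.53 with 2 of 3 TG arrays above background (adjusted p = 0.000309, blocked 6.39 with adjusted p = 0.013), and Il6 by 5.73 ± 0.82 with 1 of 3 (adjusted p = 0.00345, blocked 6.89 with adjusted p = 0.0328). Fmod was lower by at least 11.6-fold (-4.26 ± 0.33, adjusted p = 0.00014, blocked -3.83 with adjusted p = 0.013) and Comp by -4.70 ± 0.43 (adjusted p = 0.000359, blocked -4.19 with adjusted p = 0.0244). In all, 1749 genes (8.85%) passed, 1029 higher and 720 lower.

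Of 33 cytokine genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.12, or 0.87 at the bound (camera adjusted p = 2.11e-09, and adjusted p = 0.144 with an estimated correlation, blocked 1.19 with adjusted p = 5.74e-12). Il1b was at least 13.3-fold higher (4.19 ± 0.54, limma adjusted p = 0.00214, blocked 4.82 with adjusted p = 0.031). Of 14 neutrophil markers, 7 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 2.86 (or 2.02 at the bound, camera adjusted p = 4.71e-08, and adjusted p = 0.144 with an estimated correlation, blocked 3.11 with adjusted p = 3.02e-08). Of 16 stress genes, 11 rose and 0 fell (12 and 1 adjusted over the list alone). Their median was 1.11 (camera adjusted p = 9.11e-08, and adjusted p = 0.144 with an estimated correlation, blocked 1.16 with adjusted p = 7.09e-09). Examples were Nppb at 1.08 ± 0.14 and Gdf15 at 2.90 ± 0.46. Nppa went the other way without passing, at 8.88, 7.95 and 8.73 on the TG arrays and 7.39, 7.90 and 6.18 on the TG+MI arrays. Of 24 glycolysis genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 2.19e-06, and adjusted p = 0.443 with an estimated correlation, blocked 0.34 with adjusted p = 0.000114). Slc16a3 was higher by 3.03. Of 17 immediate early and heat shock genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone). Their median was 0.81 (camera adjusted p = 0.00396, and adjusted p = 0.682 with an estimated correlation, blocked 1.12 with adjusted p = 0.000114), and that call was lost without TG+MI 3 (median 0.47, adjusted p = 0.198). Single calls were fewer with the slide block, with 7 cytokine, 4 neutrophil, 1 stress, 1 glycolysis and 1 immediate early genes higher and 0 lower.

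Of 36 matrix genes, 4 rose and 12 fell (9 and 18 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 0.000204, and adjusted p = 0.547 with an estimated correlation, blocked -0.56 with adjusted p = 0.0258). Those that rose included Timp1 (3.16 ± 0.50), and those that fell included Col1a1 (-1.64 ± 0.34, lost without TG 1 with -1.39 and adjusted p = 0.0657). Of 13 fibroblast markers, 0 rose and 4 fell (0 and 9 adjusted over the list alone). Their median was -0.69 (camera adjusted p = 4.69e-07, and adjusted p = 0.144 with an estimated correlation, blocked -0.56 with adjusted p = 0.000538). Of 4 atrial markers, 0 rose and 1 fell (0 and 4 adjusted over the list alone). Their median was -6.16 (camera adjusted p = 0.00372, and adjusted p = 0.457 with an estimated correlation, blocked -6.63 with adjusted p = 0.0114). Of 9 adipocyte markers, 0 rose and 1 fell (0 and 5 adjusted over the list alone). Their median was -3.36 (camera adjusted p = 0.00175, and adjusted p = 0.443 with an estimated correlation, blocked -2.78 with adjusted p = 0.0484). Blocked for slide, 0 matrix genes rose and 3 fell, and 0 fibroblast, atrial and adipocyte markers were called. The matrix list's median deviation was -0.67 on TG+MI 3, against -0.0634 and 0.15 on TG+MI 1 and TG+MI 2.

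Of 42 Toll-like receptor genes, 3 rose and 0 fell, as when adjusted over the list alone. Their median was 0.07 (camera adjusted p = 0.278, blocked 0.04 with adjusted p = 0.195). The genes that rose were Myd88 (0.96 ± 0.15, limma adjusted p = 0.00456, blocked adjusted p = 0.123), Rel (0.72 ± 0.10, adjusted p = 0.0034, blocked adjusted p = 0.118) and Nfkb2 (0.61). Tlr2 differed by 0.17 (adjusted p = 0.776) and Tlr4 by 0.24 (adjusted p = 0.265). Of 28 macrophage markers, 2 rose and 3 fell (3 and 3 adjusted over the list alone). Their median was -0.18 (mean 0.32, camera adjusted p = 0.299), and those that fell included Cd163 (-1.31 ± 0.34). Of 40 conduction genes, 0 rose and 3 fell, as when adjusted over the list alone. Their median was -0.11 (camera adjusted p = 0.03, and adjusted p = 0.658 with an estimated correlation, blocked -0.23 with adjusted p = 0.047). Among the conduction genes was Kcne1 (-1.91 ± 0.42), and the call was lost without TG 3 (adjusted p = 0.0515). The block called 0 Toll-like receptor, macrophage and conduction genes. The oxidative phosphorylation, fatty acid oxidation and contractile lists had medians of 0.06, -0.04 and -0.03 (camera adjusted p of 0.721, 0.253 and 0.385 without the slide block). On slide 2, where TG 3 is the only TG array, the medians of these lists were -0.02, -0.14 and -0.13.

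With the slide block 119 genes were called, 105 of them shared with the 1749, and on slide 2 alone, with TG 3 as the only TG array, limma called 0 (1694 at an unadjusted p under 0.05). The count was 724, 1015 and 1135 without TG 1, TG 2 and TG 3, 690 without TG+MI 2, and 1132 without WT+MI 1 and TG+MI 2.

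The interaction asked whether the infarction response differed between transgenic and wild-type hearts, and 1758 genes (8.90%) passed, 1156 higher and 602 lower. The matrix and macrophage lists had the lowest camera p, with lower medians in the transgenic response, but passed in neither case with an estimated correlation (adjusted p of 0.172 and 0.385). Mt2 differed by -2.89 ± 0.34 (limma adjusted p = 0.0104), Hmox1 by -2.17 (adjusted p = 0.0156) and Nppa by -3.87 ± 0.55 (adjusted p = 0.0156). For Nppa and Mt2, TG was above WT by 2.82 and 2.66 without infarction, and for the matrix gene Col12a1 (adjusted p = 0.0139 in the interaction) at least 2.15-fold. Cd14 differed by -2.65 (adjusted p = 0.0277) and Il1b, which was not well above background in TG, by -2.79 ± 0.77 (adjusted p = 0.0491), and Tlr2, Tlr4 and Myd88 by -1.57, -0.42 and -0.51 without passing (adjusted p of 0.0519, 0.136 and 0.121). No slide held all 4 groups, and with the slide block 3 genes passed (3212 at an unadjusted p under 0.05), with blocked adjusted p between 0.103 and 0.292 for the named calls.

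Of 36 matrix genes, 1 was higher and 18 lower in the interaction (1 and 29 adjusted over the list alone), with a median of -1.32 (camera adjusted p = 1.17e-17, and adjusted p = 0.172 with an estimated correlation, blocked -1.24 with adjusted p = 5.07e-15). Of 28 macrophage markers, 0 were higher and 6 lower (0 and 15 adjusted over the list alone). Their median was -1.35 (camera adjusted p = 2.77e-10, and adjusted p = 0.385 with an estimated correlation, blocked -1.42 with adjusted p = 1.68e-10). Of 33 cytokine genes, 1 was higher and 5 lower (2 and 9 adjusted over the list alone). Their median was -0.85 (camera adjusted p = 7.11e-05, and adjusted p = 0.385 with an estimated correlation, blocked adjusted p = 0.000894). Of 42 Toll-like receptor genes, 2 were higher and 4 lower (3 and 7 adjusted over the list alone). Their median was -0.20 (camera adjusted p = 0.00349, and adjusted p = 0.477 with an estimated correlation, blocked -0.26 with adjusted p = 0.00342). Of 40 conduction genes, 7 were higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 0.50 (camera adjusted p = 0.0127, and adjusted p = 0.502 with an estimated correlation, blocked 0.44 with adjusted p = 0.0127). Of 4 atrial markers, 0 were higher and 1 lower (0 and 2 adjusted over the list alone). Their median was -7.78 (camera adjusted p = 0.00391, and adjusted p = 0.441 with an estimated correlation, blocked -8.28 with adjusted p = 0.00441). The block called 0 members of these lists. The count of 1758 fell to 192, 60 and 58 without WT 1, WT 2 and WT 3, 389 and 672 without WT+MI 1 and WT+MI 2, 134 and 204 without TG 1 and TG 2, 81 and 941 without TG+MI 1 and TG+MI 3, and was 2691 without TG+MI 2.

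Across 19761 genes, which are not independent replicates, the infarction responses of wild-type and transgenic hearts, which share no array, correlated with Pearson r = 0.57 and Spearman rho = 0.50. The total least squares slope of the transgenic on the wild-type response was 0.46, and 814 genes were higher in both (191 in independent lists of these sizes) and 464 lower in both (211), against 9 and 26 with opposite calls. The wild-type response and the difference of TG+MI from WT+MI, which share the WT+MI arrays, correlated with r = -0.82 (rho = -0.81), where 100 simulations of unchanged groups gave -0.50. The simulated groups held no infarction response, so this value and the simulated 0.50 below are not levels to set r against. Covariances are given instead: that of the response and this difference was -0.416 against a simulated -0.032, a difference of -0.384. The simulated noise was independent between genes and equal in spread between groups. The WT+MI arrays, however, lay at 107, 70.1 and 57.2 on the first principal component. A shift that many genes share on these arrays can enlarge such a covariance, so the simulated covariances are not bounds for unchanged groups. Of the genes that rose with infarction, 809 were lower in TG+MI than in WT+MI (161 in independent lists), and of those that fell, 1417 were higher (451). The wild-type response and the difference of TG from WT, which share the WT arrays, correlated with r = 0.32 (rho = 0.36, simulated 0.50), with a covariance of 0.152 against a simulated 0.032, and 133 genes were higher in both (54.7) and 142 lower in both (65.6). Part of these overlaps may come from the shared arrays. The differences of TG from WT and of TG+MI from WT+MI correlated with r = -0.10 (rho = -0.15), with 21 genes higher in both (22.9) and 17 lower in both (9.82).

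**Figure D3:**
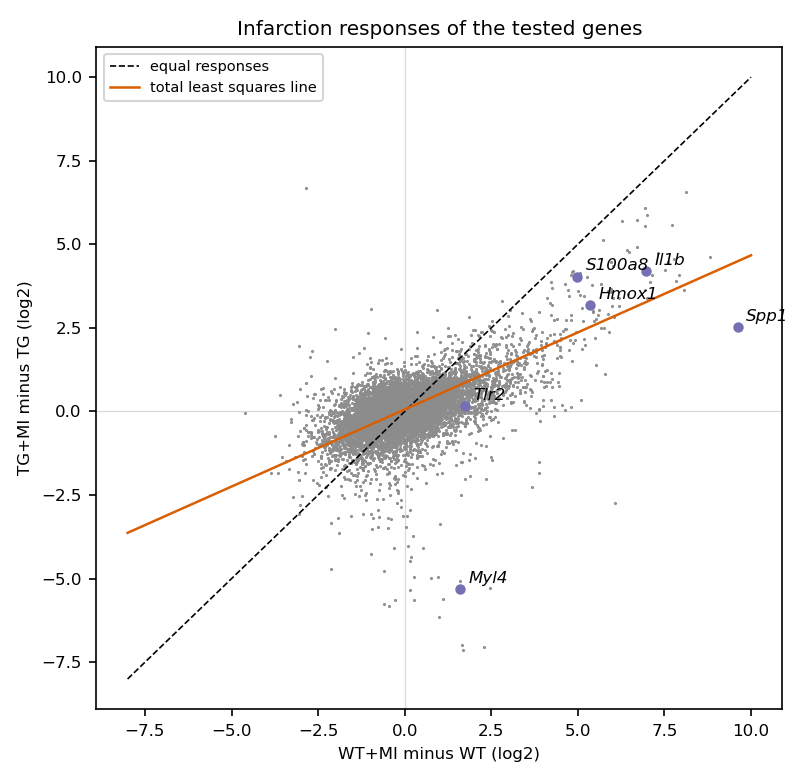
Log2 difference of WT+MI from WT (horizontal axis) against that of TG+MI from TG (vertical axis), with a point per tested gene, a line of equality and a total least squares line. The total least squares slope was 0.46, and Spp1, Il1b, S100a8, Hmox1, Myl4 and Tlr2 are labelled.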

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

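The tests of slide, of the cytokine list's kept fraction, of a standing transgene effect, of atrial tissue as given here, of TG as the base, of the chromosome 6 window as given here and of other splits were chosen after the results they bear on were seen, and the tests of infarct share and valve markers were chosen before their own results but after the patterns had been seen.

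The infarction response differed between transgenic and wild-type hearts by limma's interaction test for 1758 genes and by camera for 19 gene lists. With an estimated correlation 0 of the 19 lists held, by fry 2 held, and with the slide block 3 genes passed. Medians of the lists were below 0 for extracellular matrix (-1.32), monocytes and macrophages (-1.35), immediate early and heat shock genes (-1.51, camera adjusted p = 1.55e-08, and adjusted p = 0.385 with an estimated correlation), cardiac stress (-0.86, adjusted p = 1.07e-06 and 0.172), cytokines (-0.85), antigen presentation (-1.09, adjusted p = 0.000565 and 0.502), cell death (-0.54, adjusted p = 0.000565 and 0.385), inflammasome (-0.56, adjusted p = 0.000886 and 0.385), Toll-like receptors (-0.20) and atrial markers (-7.78). They were also below 0 for interferon-stimulated genes (-0.25, adjusted p = 0.00883 and 0.663), adipocytes (-4.16, adjusted p = 0.00883 and 0.477), epicardium (-1.44, adjusted p = 0.0173 and 0.385) and neutrophils (-0.93, adjusted p = 0.0282 and 0.502). They were above 0 for oxidative phosphorylation (0.47, adjusted p = 1.23e-05 and 0.531), contractile genes (0.43, adjusted p = 0.00561 and 0.652), fatty acid oxidation (0.56, adjusted p = 0.00561 and 0.66), conduction (0.50) and erythroid markers (2.32, adjusted p = 0.0127 and 0.531). With the slide block, 3 of these lists did not pass: epicardium (adjusted p = 0.0768), adipocytes (adjusted p = 0.0602) and erythroid markers (adjusted p = 0.0973). Calls were lost without TG+MI 3 for fatty acid oxidation (adjusted p = 0.0612), contractile genes (0.0533), erythroid markers (0.0596) and interferon-stimulated genes (0.189), the last also without WT 1 (0.0518) and WT+MI 1 (0.174, at a median of -0.0749). The neutrophil call was lost without WT 3 (adjusted p = 0.0536), WT+MI 1 (0.0986), TG 3 (0.061) and TG+MI 1 (0.0637), at medians of -0.62, -0.43, -0.66 and -0.52. An interaction can also come from a difference between TG and WT without infarction. For atrial markers the medians of TG against WT and of TG+MI against WT+MI were 8.26 and 0.47. In the same order they were 3.40 and 0.01 for adipocytes and -2.10 and 0.14 for erythroid markers. For extracellular matrix they were 0.96 and -0.47, for macrophages 0.28 and -1.10, and for cytokines -0.16 and -1.08.

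Single genes that differed, well above background on at least 1 array of each group, included Cenpf (3.40), Olfr1466 (2.88), Irx1 (2.46), Armc2 (2.44), Cxcl14 (2.19), Ndufa9 (0.83), Ripk1 (-0.70), Trem2 (-1.96), Dusp1 (-1.99), Hmox1 (-2.17), Cd14 (-2.65), Mt2 (-2.89), Nr4a1 (-2.92), Nppa (-3.87), Spp1 (-7.10) and Cyp2e1 (-7.15). For others at least 1 group had no array well above background, so their values rest partly on background signal and have no order: Kcnj4 (3.07), Cmtm2b (2.96), Rfx5 (2.58), Mybphl (-9.34), Hamp (-8.82), Tmem163 (-7.74), Mlana (-6.67), Msln (-5.93), Cilp2 (-5.90), Ptgs2 (-4.67), Col12a1 (-3.36), Fmod (-3.28) and Il1b (-2.79). Limma's adjusted p lay between 0.0104 and 0.0491 for these genes and between 0.103 and 0.292 with the slide block. Leaving out each array in turn ended 0 of the calls of Mlana, Cilp2, Col12a1, Fmod, Mt2, Hmox1 and Nppa. Of these genes, Mlana, Cilp2, Col12a1, Fmod, Mt2 and Nppa were also higher in TG than in WT without infarction.

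The lower inflammatory and higher ion channel lists in TG+MI than in WT+MI may reflect the slide, a smaller share of infarcted tissue or the transgene. If genes rose in infarcted tissue alone, a smaller share would leave every raised group the same fraction of its linear rise over WT. However, 4 of 12 lists lay apart from all 1507 raised genes (0.336, 95% bootstrap interval over genes 0.322 to 0.352). They were neutrophil markers at 0.135, and stress, glycolysis and immediate early genes at 0.573, 0.526 and 0.627. With TG as the base immediate early genes no longer lay apart (0.16, 0.336 and 0.989 on the TG+MI arrays), but neutrophil, stress and glycolysis genes did again. Macrophage markers lay apart too (0.177). These fractions argue against infarct share as the whole cause only if the raised genes rose in infarcted tissue alone. That premise was not tested, so infarct share stays open. For the cytokine list infarct share stays open even under that premise, since the list's fraction of 0.282 had an interval of 0.156 to 0.412. Slide and transgene cannot be told apart: the blocked cytokine median was -0.92, but the block rests on TG 3, kept the sign of 99.8% of the 2405 calls and raised the median standard error from 0.171 to 0.311, and 0 genes passed in limma (1469 at an unadjusted p under 0.05).

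The higher matrix, atrial and adipocyte lists in TG than in WT may come from other tissue in the samples or from the transgene, which cannot be told apart from strain here. If atrial tissue brought the other genes, they would be raised on WT+MI 1 and TG+MI 2, where atrial markers exceeded the other arrays of the group by 8.66 and 5.06. The 292 genes raised in TG outside the atrial list, Nppa among them, had a median of 1.33 in TG against WT. On these arrays their medians were 0.13 (0.07 to 0.18) and -0.10, and those of the adipocyte list -0.42 and -0.58. This argues against atrial tissue for these genes as a set, but weakly, since each value sets 1 array against 2. The atrial signal there was also mostly below that of TG, so atrial tissue would raise the other genes less. Myl4 read 7.15 on WT+MI 1 and 5.27 on TG+MI 2, against 9.05, 6.90 and 8.66 on the TG arrays. The values on TG+MI 2 therefore decide little. WT+MI 1 also lay furthest from WT on the first principal component. Atrial tissue stays open for the matrix list (0.0937 and 0.44, the latter with an interval of 0.08 to 0.62) and for the atrial markers themselves (8.26 in TG against WT). A standing transgene effect would raise the genes higher in TG after infarction too. The 294 such genes (median 1.36) had a median of 0.0337 (-0.03 to 0.08) in TG+MI against WT+MI, with 21 higher and 9 lower. As a set they were thus not higher after infarction. But the genes were picked for being high in TG, and TG+MI and WT+MI share no slide, so a standing effect is not excluded. Valve or cartilage-like tissue stays open: 19 tested markers of 26 had a median of 0.60 (0.22 to 1.11), and 2 passed singly, Cilp (2.23) and Prg4 (2.55), and so does a transgene effect in hearts without infarction alone, as untested.

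Gt(ROSA)26Sor, whose brightest probe lies on chromosome 6 at 113020400 to 113020459 (mm9), read 2.09, 2.16 and 2.27 in WT, 2.60, 2.39 and 2.62 in WT+MI, 2.75, 4.59 and 2.75 in TG, and 5.0, 5.56 and 6.62 in TG+MI. Slide is argued against as the whole cause, though weakly. The lowest of TG 1 and TG 2 exceeded the highest WT array by 0.48 on the same slide, though in another row of it. In TG against WT, however, the gene did not pass (1.19, limma adjusted p = 0.236). The transcripts Setd5 (0.72), AK076574 (0.82) and AK042057 (1.33) within 100 kb were also higher in transgenic hearts and were singled out after their values were seen. A genotype difference tied to this place, as from an insertion there, stays open: apart from these 4 and Srgap3, seen before, 6 of 33 genes within 1 Mb (18.2%, exact 95% interval 6.98% to 35.5%) had an unadjusted p under 0.05 for genotype, against 21.2% in the median of 18964 random windows, so the genes left argue neither for it nor, with called neighbours left out, against it. The other 2 probes of Gt(ROSA)26Sor were dim and did not follow the first in TG. Genotype calls clustered as much elsewhere. The 1 Mb stretch that holds the gene had 4 calls among 27 genes, against 5 among 20 in a stretch of chromosome 16 and 5 among 15 in one of chromosome 9.

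With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each pairwise comparison 1 of the 10, the labelled one, gave as many genes. The labelled counts and the highest of the others were 9464 and 0 for WT+MI against WT, 518 and 1 for TG against WT, 2405 and 9 for TG+MI against WT+MI, and 1749 and 0 for TG+MI against TG. For the interaction, genotype was split anew within infarction status. Of 100 drawn splits 1, the labelled one, gave as many genes as 1758, with 339 as the highest other. The labelled split was always among the 100, so this is the lowest share they could give. The other splits mix genotype differences into the spread, so their counts do not exclude chance. Among infarcted arrays the labelled split is also that of the slides. Splits of all 12 arrays, which mix the infarction response into the spread, decide nothing: 87 of 100 gave 0 genes and 3 gave more than the labelled one, up to 3323.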

How the results depend on the processing

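The removal of pairs of arrays that stood apart was tested after the results were seen. The count for WT+MI against WT stayed within 1.5 times of 9464 except at a log2 difference of at least 1 (3230) or an adjusted p under 0.01 (5890), whose construction makes them smaller. The other counts, in the order TG against WT, TG+MI against WT+MI, TG+MI against TG and interaction, were 205, 14, 955 and 55 with no filter on dim probes, 320, 0, 119 and 3 with the slide block, 1941, 8105, 4499 and 6584 with array weights, 317, 719, 739 and 1013 at a log2 difference of at least 1, and 107, 0, 417 and 9 at an adjusted p under 0.01. With only the groups compared in the fit they were 904, 0 and 690 for the pairwise comparisons, and on slide 2 alone 0 for TG+MI against TG. Where limma called 0 genes in TG+MI against WT+MI, 1469, 6617 and 4774 had an unadjusted p under 0.05 with the slide block, at an adjusted p under 0.01 and with only these groups, and 1694 did so for TG+MI against TG on slide 2. Leaving out each array in turn gave 137 to 866, 0 to 3524, 690 to 2286 and 58 to 2691. Leaving out WT+MI 1 and TG+MI 2 gave 1132 for TG+MI against TG, and leaving out TG 1 and TG+MI 3 gave 0 for TG+MI against WT+MI (6029 at an unadjusted p under 0.05) and 294 for the interaction. The cause of the other changes was not tested. With no filter, the share of higher genes among calls moved from 64.0% to 35.7% for TG+MI against WT+MI and from 65.8% to 36.4% for the interaction.

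No pairing of the samples by replicate number was seen: of 18 same-number pairs, 1 had a correlation of deviations over 0.1 (range -0.26 to 0.12), and 2 of 12 arrays matched their own number best. With 3 arrays per group and some that stood apart, a pairing is not excluded. With the replicate block 342 genes were called for TG against WT and 1156 for the interaction, the other counts stayed within 1.5 times, and 132 of 149 named calls and all 75 list calls were kept. The correlation of the infarction responses was 0.28 with no filter, 0.63 with the slide block and 0.46 to 0.63 over the leave-outs, and that of the wild-type response with TG+MI minus WT+MI -0.70, -0.66 and -0.86 to -0.76. The Toll-like receptor list in TG+MI against WT+MI kept its median below 0 throughout but not its call with no filter (-0.26, adjusted p = 0.0887), or, at its median of -0.24, with an estimated correlation (adjusted p = 0.386) or by fry (adjusted p = 0.0934), and leave-outs gave -0.28 to -0.10. Of the other 75 list calls, 0 held with an estimated correlation, 28 by fry, 65 with the slide block, 59 with no filter, 63 with array weights and 864 of 900 over the leave-outs. Calls were also gained: of 69 list tests without a call, 6 passed with the slide block and 11 with no filter. The contractile list in TG against WT turned to -0.0112 (adjusted p = 0.729) with quantile normalization and 0.0898 (adjusted p = 0.221) in the authors' table. Of 149 named calls, 61 were kept with the slide block, 86 lost and 2 reversed, Tmem238l (-0.0469) and Olfr531 (-0.16) in TG+MI against WT+MI, not well above background in WT+MI, 84 were kept with no filter, and 1388 of 1788 over the leave-outs. Signal over background limits dim genes, whose differences are bounds.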

Other observations

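No test in this part was chosen after its result was seen, but the lists given are those not yet described, and the genes named as examples were picked from the results. Of 16 circadian clock genes, 2 rose and 7 fell in WT+MI against WT (3 and 7 adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.246). Examples were Dbp at -2.95 ± 0.34 and Per3 at -2.42 ± 0.32 (n = 3 per group, limma adjusted p = 0.000198 and 0.000382). In TG+MI against TG, 1 rose and 5 fell (2 and 8 adjusted over the list alone). Their median was -0.72 (camera adjusted p = 0.0113, and adjusted p = 0.547 with an estimated correlation, blocked -0.76 with adjusted p = 0.0484). Dbp was lower by -2.52 ± 0.34 there and Arntl, the core activator also called Bmal1, higher by 1.88 ± 0.23, and the list call was lost without TG+MI 1 (median -0.36, adjusted p = 0.0695). With the slide block 0 clock genes were called in TG+MI against TG. The time of day of sampling is not given in the sources used here. Of 26 cell cycle genes, 3 rose and 12 fell in WT+MI against WT (3 and 14 adjusted over the list alone). Their median was -0.57 (camera adjusted p = 0.184). Examples were Cenpf at -3.11 ± 0.41 and Mki67 at -1.45, while the replication genes Mcm3 and Mcm6 rose by 0.86 and 0.93. The cell cycle list was also lower in TG against WT (median -0.30, 0 rose and 1 fell, as when adjusted over the list alone, camera adjusted p = 0.00576, and adjusted p = 0.588 with an estimated correlation, blocked -0.29 with adjusted p = 0.0266, lost without WT 1 at -0.24 with adjusted p = 0.0672), in TG+MI against TG (median -0.32, 0 rose and 1 fell, 1 and 7 adjusted over the list alone, camera adjusted p = 0.0225, and adjusted p = 0.682 with an estimated correlation, blocked adjusted p = 0.0606, lost without TG+MI 1 at -0.20 with adjusted p = 0.0613) and in TG+MI against WT+MI (median -0.14, 1 rose and 1 fell, as when adjusted over the list alone, camera adjusted p = 0.0239, and adjusted p = 0.654 with an estimated correlation, blocked adjusted p = 0.104, lost without WT+MI 3, where the median turned to 0.0321 with adjusted p = 0.474, and TG+MI 2, at -0.0639 with adjusted p = 0.0659).

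Of 12 smooth muscle and pericyte markers, 3 rose and 0 fell in TG against WT (4 and 2 adjusted over the list alone). Their median was -0.02 (with a mean of the opposite sign, camera adjusted p = 0.309), and Cnn1, Tagln and Myh11 were higher by 3.58 ± 0.68, 2.10 and 1.75. In TG+MI against TG, 0 rose and 5 fell, as when adjusted over the list alone. Their median was -0.13 (camera adjusted p = 0.0293, and adjusted p = 0.443 with an estimated correlation, blocked -0.20 with adjusted p = 0.177, lost without TG 2 at -0.0751 with adjusted p = 0.0674 and TG+MI 3 at -0.26 with adjusted p = 0.0655). Examples were Cnn1 at -2.51 ± 0.68 and Myh11 at -1.85, and with the slide block 0 of these markers were called here and 3 in TG against WT. Of 13 resident fibroblast markers, 1 rose and 6 fell in WT+MI against WT, as when adjusted over the list alone. Their median was -0.75 (camera adjusted p = 0.213). An example was Scara5 at -2.42 ± 0.34. Between TG+MI and WT+MI, 1 fibroblast marker rose and 0 fell, as when adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.706 without the slide block). Of 24 glycolysis and hypoxia genes, 0 rose and 2 fell in TG+MI against WT+MI (0 and 1 adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.00303, and adjusted p = 0.574 with an estimated correlation, blocked -0.28 with adjusted p = 0.000299), and 0 rose and 1 fell in TG against WT (1 and 3 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.0364, and adjusted p = 0.628 with an estimated correlation, blocked -0.31 with adjusted p = 0.0266, lost without WT 2 at -0.23 with adjusted p = 0.0719 and TG 1 at -0.17 with adjusted p = 0.0951). In TG+MI against WT+MI, 0 of 17 immediate early and heat shock genes passed (median -0.42, camera adjusted p = 0.0095, and adjusted p = 0.706 with an estimated correlation, blocked -0.08 with adjusted p = 0.543, lost without WT+MI 1, TG+MI 1 and TG+MI 2 at medians of -0.0640, -0.17 and -0.32 with adjusted p of 0.276, 0.207 and 0.0767), and 0 of 31 interferon-stimulated genes (median -0.12, camera adjusted p = 0.0239, and adjusted p = 0.766 with an estimated correlation, blocked adjusted p = 0.191, lost with a change of sign without WT+MI 1, at 0.0450 with adjusted p = 0.683, and TG+MI 3, at 0.0723 with adjusted p = 0.758). With the slide block 0 cell cycle, glycolysis and lymphocyte genes were called in TG against WT and 0 cell cycle genes in TG+MI against TG. Of 14 lymphocyte markers, 0 rose and 1 fell in TG against WT (0 and 2 adjusted over the list alone). Their median was -0.30 (camera adjusted p = 0.0364, and adjusted p = 0.594 with an estimated correlation, blocked -0.34 with adjusted p = 0.0631), and that call was lost without WT 1, TG 1 and TG 3 (medians of -0.0906, -0.23 and -0.34, adjusted p of 0.546, 0.0989 and 0.0631). In WT+MI against WT the medians of the endothelial, skeletal muscle, lung, erythroid, epicardial, sex-linked and interferon-stimulated lists were 0.00, -0.18, 0.66, -1.64, 3.65, -0.14 and 0.31, and none of these passed in camera (adjusted p of 0.924, 0.542, 0.0605, 0.107, 0.0687, 0.956 and 0.0747).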
